A study of Danio rerio with 6 samples.

How the data were processed

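RNA-seq was carried out on zebrafish (Danio rerio) tissue lying posterior to the last somite, taken at 16 hours post fertilisation. Per the labels' protocols, RNA was extracted with Trizol and an RNeasy micro kit, and strand-specific Illumina libraries were made from polyadenylated RNA. The 6 libraries form 2 groups of 3. The sall4 morphant group came from embryos injected with a sall4 morpholino, an antisense oligomer that blocks translation or splicing of its target. In the control group 1 library, control replicate 1, came from embryos injected with a scrambled morpholino, and replicates 2 and 3 came from embryos that were not injected. The design text of the series treats these 3 as 1 control group, and so did the main comparison here. The labels do not say whether the libraries of a group came from separate clutches, so p-values measure the spread between these samples, which may be technical in part.

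The deposited counts are whole numbers per Ensembl gene, 1 column per sample, for 32520 genes. The submitters' processing notes name STAR 2.7.10a, DESeq2 1.38.3 and the genome build GRCz11 without giving their roles. The counting tool, its strand setting and the annotation release are not given in the sources used here. Counts of near-identical paralogues, such as the embryonic globin genes, and of overlapping or antisense genes are therefore uncertain. The deposited FPKM values equal the counts divided by a gene length and by 1 scale per sample, as was checked from their ratios. These scales followed median-of-ratios size factors and not the column totals. No row without a gene was present. Gene names were those paired with the identifiers in the files. A name occurred again in 721 rows, and every row of a name was used as a list member. The reference gene table supplied for this work belongs to another assembly (GRCz12tu), so no coordinates are printed, and GC content was not examined.

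Total counts per sample ranged from 18626513 to 42423495. Genes were kept by edgeR's filterByExpr with the group as factor, which left 17803 genes. Counts were normalised by TMM and fitted with edgeR 4.0.16 (R 4.3.3) as a quasi-likelihood model with the group as the only term. P-values come from the quasi-likelihood F test and are two-sided, and adjusted p-values are Benjamini-Hochberg values over all tested genes with a threshold of 0.05. The standard error of a log2 fold change is its size divided by the square root of F. Levels are CPM on TMM-scaled library sizes, as mean ± SD over 3 libraries. Log2 fold changes are morphant minus control. Under this scaling the median log2 fold change of all tested genes was 0.12, and changes are to be read against that value.

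Before the data were examined, 28 gene lists were fixed for the tissue, the target and the other cell types the piece could hold. They were tested with limma's camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01. Camera asks whether a list moved relative to the other genes, and its adjusted p is over the 28 lists. Estimated correlations and fry, which asks whether a list's genes moved one way on balance, were run as alternatives. The genes named were fixed by a rule made at the same time. It names sall1a, sall1b, sall3a, sall3b, sall4, tbxta, tbx16, sox2, msgn1 and cdx4. It adds, among genes past the threshold with an average log2 CPM of at least 1, non-overlapping groups and a symbol that is not a clone name, up to 8 with the largest rise and 8 with the largest fall. It further adds the members with the smallest adjusted p in each list, up to 3 where a member passed the threshold over all genes and otherwise 2. Other genes are said to have been chosen after their values were seen. The scrambled-injected control was set against the non-injected controls without a test, and list medians were placed among 10000 random lists of the same size matched on mean expression.

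Alternatives fixed before the data were examined were a replicate block, median-of-ratios size factors, library-size scaling, no filter and a stricter filter, DESeq2 1.42.0, robust edgeR settings, a fold floor of 1.5, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1), each kind of control alone, a design with 3 levels, and each library left out in turn. After the data were seen, removal of a trend on gene length (a lowess curve per library, span 0.3, on lengths relative to the median derived from counts and FPKM), the same without morphant replicate 2, voom with library quality weights, and 1 surrogate variable (sva 3.50.0) were added. The same seed gives the same results in each run. Figures were drawn with matplotlib 3.10.9.

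The fits were tested on simulated counts drawn from the real means, library sizes and dispersions. For 3 morphants against 3 controls, over 17803 genes with 50 changed at each fold size, edgeR recovered 4% of the 2-fold, 56% of the 4-fold, 94% of the 8-fold and 100% of the 16-fold changes and called 2 unchanged genes. DESeq2 recovered 20%, 80%, 96% and 100% and called 40 unchanged genes. For 2 morphants against 3 controls, without morphant 2, over 18125 genes, edgeR recovered 42% of the 2-fold and 96% of the 4-fold changes and called 30 unchanged genes. These draws were independent between genes, used the same dispersion of a gene in both groups and held no length trend. Changes were placed only in genes with a mean of at least 2 CPM. The real morphants spread more than the controls and carry length trends, so these rates do not check the calls on the real counts. A separate simulation of 3 morphants against 3 controls over 17625 genes used a common dispersion and drew the genes independently. In it a list made to fall by 0.6 on the log2 scale was called with a median of −0.60, and no other list was called. Removing a simulated length trend left a median of −0.56. Estimated correlations in the real lists reached 0.86 (ribosomal protein genes), so this simulation does not check list calls where members move together.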

Results

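Gene expression was measured by RNA-seq in the tissue behind the last somite of zebrafish embryos at 16 hours post fertilisation, a region that holds the tailbud, the presomitic mesoderm and the caudal ends of the neural tube and notochord. Morphants that had received a morpholino against sall4, a zinc finger transcription factor gene, were compared with controls, with 3 libraries in each group. The control group consisted of 1 library from embryos injected with a scrambled morpholino and 2 libraries from embryos that were not injected. Total counts were 19718510 in control 1 (scrambled), 18687559 in control 2 and 42423495 in control 3, and 18626513, 22588689 and 25144393 in morphants 1, 2 and 3. Reads were found for 21538 to 24721 genes per library. P-values measure only the spread between these samples, since separate clutches are not stated.

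The transcript of the target, sall4 (ENSDARG00000044485), was abundant in every library. It was measured at 1110 CPM in control 1, 1312 in control 2 and 1347 in control 3, and at 974.5, 1337 and 1390 CPM in morphants 1, 2 and 3. The log2 fold change was −0.03 (SE 0.27, edgeR adjusted p = 0.97), smaller than the spread between replicates, and its sign differed between settings, with a range from −0.12 to 0.45. A morpholino that blocks translation need not lower its target's transcript, so this value does not check the injection. Of the other sall genes, sall3b stood at 65.5 ± 18.1 CPM (SD, n = 3) in controls and 153.9 ± 55 in morphants, with all morphants above all controls. Its log2 fold change of 1.23 (SE 0.35) did not pass the threshold (edgeR adjusted p = 0.33). The values of sall3a were 3.16 ± 0.63 and 1.46 ± 1.22 CPM (adjusted p = 0.58), and those of sall1a were 109.3 ± 10.3 and 121.4 ± 55.4 CPM (adjusted p = 0.87). The low counts of sall1b kept it out of the tested genes.

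**Figure D1:**
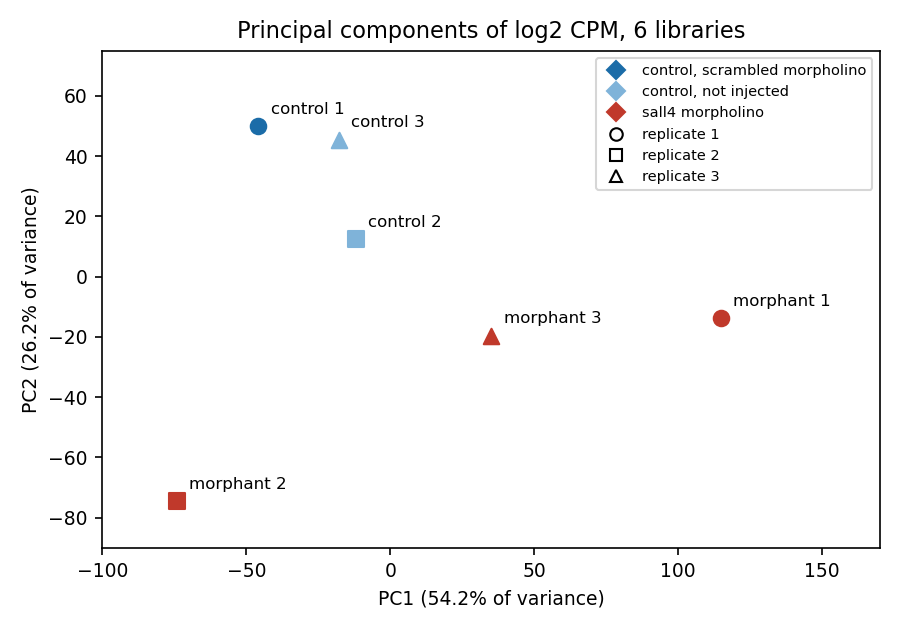
Principal components of log2 CPM over the tested genes, with component 1 (54.2% of the variance) on the horizontal and component 2 (26.2%) on the vertical axis, 1 point per library, coloured by injection and shaped by replicate. Morphant 1 at 114.7 and morphant 2 at −74.1 lie at the ends of component 1, and the 3 controls lie between −45.8 and −11.9. On component 2 the controls lie between 12.4 and 49.9 and the morphants between −74.5 and −13.8.

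The morphant libraries differed more from one another than the controls did. The median within-group SD of log2 CPM was 0.59 in morphants and 0.25 in controls. Between morphants 1 and 2, 9046 genes differed by more than 2-fold, against 871 to 1765 between pairs of controls. Mitochondrial mRNA took 5.04%, 6.68% and 6.03% of counts in controls 1 to 3 and 9.50%, 4.44% and 8.77% in morphants 1 to 3. Long genes were low in morphant 1 and high in morphant 2, with a Spearman correlation across genes between relative length and deviation from the mean of the 6 libraries of −0.42 and 0.43. The correlations were −0.28 in morphant 3 and 0.21, −0.01 and 0.04 in controls 1 to 3 (genes are not independent replicates).

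**Figure D2:**
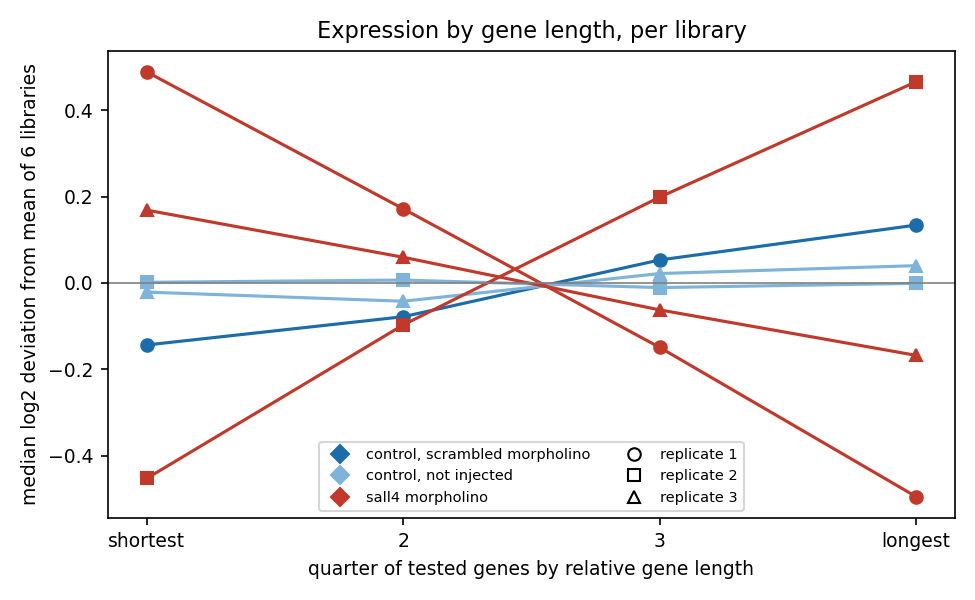
Median log2 deviation from the mean of the 6 libraries (vertical) in 4 equal bins of the tested genes ordered by relative gene length (horizontal), 1 line per library. In the bin of longest genes the median was −0.49 in morphant 1 and 0.47 in morphant 2, and between −0.0009 and 0.13 in the controls.

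The comparison of sall4 morphants with controls asks which transcripts of the caudal region differ when sall4 is targeted. Of the 17803 tested genes 5 passed the threshold, all of them higher in morphants. The transcript of adra1ba (ENSDARG00000011317), an alpha-adrenergic receptor, stood at 0.195 ± 0.050 CPM in controls and 9.59 ± 1.70 CPM in morphants (SD, n = 3), a log2 fold change of 5.54 (SE 0.41, edgeR adjusted p = 0.013). The gene col18a1b (ENSDARG00000095901), encoding a chain of a basement membrane collagen, rose from 1.85 ± 0.96 to 38.5 ± 11.3 CPM, a log2 fold change of 4.39 (SE 0.47, adjusted p = 0.042). Lubricin, encoded by prg4a (ENSDARG00000010482), rose from 0.641 ± 0.247 to 11.9 ± 2.26 CPM, by 4.22 (SE 0.41, adjusted p = 0.036). The vasopressin receptor gene avpr1ab (ENSDARG00000045788) rose by 3.94 (SE 0.41, adjusted p = 0.042). The gene tph1b (ENSDARG00000036082), encoding a tryptophan hydroxylase of serotonin synthesis, rose from 4.67 ± 0.35 to 31.6 ± 2.67 CPM, by 2.76 (SE 0.27, adjusted p = 0.036). Each of the 5 was higher in 3 of 3 morphants than in any control.

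**Figure D3:**
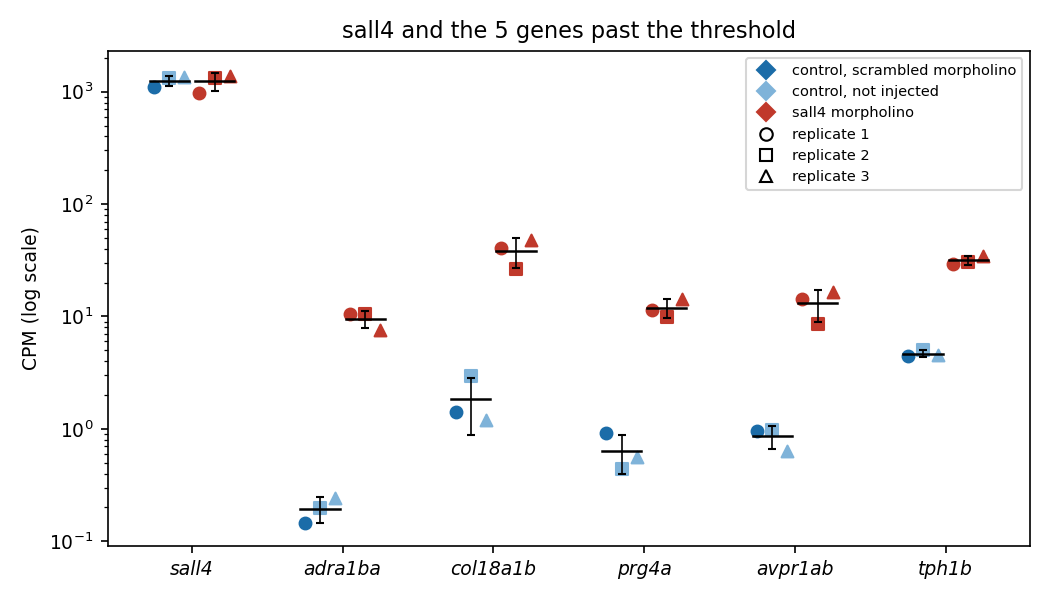
CPM on a log scale (vertical) of sall4 and of the 5 genes past the threshold (horizontal), 1 point per library, with horizontal lines at group means and bars of 1 SD (n = 3). The morphants lie above all controls for the 5 genes, for example 29.5 to 34.6 against 4.44 to 5.07 CPM for tph1b, and overlap with them for sall4.

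By edgeR, 0 genes were lower past the threshold, while 1719 genes had an unadjusted p under 0.05 (890 would by chance), 924 of them lower. Of the other splits of the 6 libraries into 3 and 3, those that set controls 1 and 3 with morphant 2, or controls 1 and 2 with morphant 2, against the rest gave more such genes, 3371 and 1913. DESeq2 called 180 genes higher and 154 lower, the 5 among them. In 17.0% of tested genes the groups did not overlap, against 10% by chance for 3 against 3. The count depended on single libraries. It was 0 without control 1, 2 or 3 or morphant 3, 19 (18 higher) without morphant 1 and 1534 (742 higher, 792 lower) without morphant 2, and the last 2 counts included the 5 genes. Without morphant 2, long genes were low in both morphants left (correlations with relative length −0.42 and −0.28, against 0.21, −0.01 and 0.04 in controls 1 to 3). Length and group thus ran together in that fit. With the length trend removed as well, a step added after the data were seen, 1042 genes passed. Over all 24 alternatives the log2 fold changes ranged from 2.81 to 5.98 for adra1ba, 3.00 to 5.10 for col18a1b, 2.46 to 4.54 for prg4a, 1.64 to 4.51 for avpr1ab and 2.33 to 2.91 for tph1b.

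Genes of neural progenitors were lower in the morphants. The spinal cord progenitor list had 28 tested members with a median log2 fold change of −0.58 (camera adjusted p = 1.6e-05, and adjusted p = 0.50 with an estimated correlation). By edgeR no member passed over all genes, and adjusted over the list alone 5 were lower and 1 was higher. By DESeq2 over all genes 5 were lower and 1 was higher, the same 6 genes. The glial and radial progenitor gene gfap stood at 14.6 ± 1.71 CPM in controls and 3.40 ± 0.91 in morphants, a log2 fold change of −2.10 (SE 0.33). The homeobox gene nkx6.2 stood at 47.6 ± 0.89 and 13.7 ± 3.78 CPM, a log2 fold change of −1.80 (SE 0.30). Over all genes their adjusted p-values were 0.12 and 0.13 by edgeR and 9.7e-06 and 9.4e-05 by DESeq2. The other 4 members past the threshold over the list alone were chosen after their values were seen. They are sox21a (−2.57), sox21b (−1.41), irx3a (−1.11) and zic1, which went the other way (2.21). All morphants were below all controls for 10 members. The sox2 transcript, present in neural and neuromesodermal progenitors, stood at 211.0 ± 23.5 and 212.3 ± 111.1 CPM.

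Neuronal differentiation genes were lower as a list (21 members, median −0.31, camera adjusted p = 0.0076, and adjusted p = 0.50 with an estimated correlation). By edgeR no member passed over all genes and 0 passed adjusted over the list alone, while DESeq2 called 1 lower, elavl3 (adjusted p = 0.035). The neuronal RNA-binding protein gene elavl3 had 97.7 ± 19.6 CPM in controls and 40.2 ± 11.3 in morphants (log2 fold change −1.28, SE 0.31), and the proneural gene neurod1 had 11.7 ± 1.06 and 5.84 ± 1.14 CPM (−1.005, SE 0.30). Their edgeR adjusted p-values were 0.25 and 0.35. The neural list medians lay lowest in morphant 2, at −0.97 for spinal cord progenitors and −0.82 for neuronal differentiation. The neuronal median was −0.32 in morphant 3 and −0.07 in morphant 1, the latter within the range of the controls (−0.09 to 0.12). Without morphant 2 the progenitor median was −0.37 (camera adjusted p = 0.041) and the neuronal median −0.20 (adjusted p = 0.31). The neuronal call was also lost without control 2 (median −0.31, adjusted p = 0.060) and with no filter on counts (−0.30, 0.10) or FPKM (−0.18, 0.10), and 15 of 24 alternatives kept it. The fit against the scrambled control alone, a lone library assumed to vary like the morphants, counts among the losses although its median was −0.39.

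The neural crest list was lower as well (17 members, median −0.16 and mean −0.43, camera adjusted p = 0.0067, and adjusted p = 0.50 with an estimated correlation). By edgeR no member passed over all genes, and adjusted over the list alone 4 were lower and 0 higher. DESeq2 called 3 lower over all genes, sox10, snai1b and sox9b. The crest regulator sox10 stood at 24.8 ± 5.79 CPM in controls and 5.15 ± 2.30 in morphants (log2 fold change −2.27, SE 0.43, edgeR adjusted p over all genes 0.18). The gene snai1b stood at 126.0 ± 24.8 and 49.0 ± 14.0 CPM (−1.36, SE 0.32, adjusted p = 0.22). The others, chosen after their values were seen, are sox9b (−1.43) and crestin (−1.04). Without morphant 2 the list's median was −0.34 (adjusted p = 0.10), and without morphant 3 it was −0.46 (adjusted p = 0.0012). The call was also lost with voom quality weights (−0.14, adjusted p = 0.23) and with the length trend removed without morphant 2 (−0.17, 0.12), both added after the data were seen, and 19 of 24 alternatives kept it.

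Genes of the notochord and floor plate (26 members, median −0.26, camera adjusted p = 0.0070) and of wnt signalling (28 members, median −0.20, adjusted p = 0.0089) were also lower, as were notch targets (31 members, median −0.18, adjusted p = 0.019). With an estimated correlation the adjusted p was 0.50 for each, a value tied by the Benjamini-Hochberg adjustment. The estimates were −0.006 for notochord and 0.013 for wnt, near the preset 0.01, and 0.068 for notch. For notochord and wnt, correlation between members therefore does not account for the loss of the call. Adjusted over the list alone, 1 of these members passed, notum1a, a secreted wnt antagonist, at 49.1 ± 13.5 CPM in controls and 10.8 ± 4.13 in morphants (log2 fold change −2.19, SE 0.39, adjusted p over all genes 0.16 by edgeR and 0.00016 by DESeq2). The members with the smallest p were otherwise foxa1 (−0.94, SE 0.25) and foxj1a (−1.06, SE 0.32), the latter a regulator of motile cilia, then tcf7 (−0.95, SE 0.27), nrarpb (−0.97, SE 0.26) and hey2 (−0.58, SE 0.27). The notochord call was lost without morphant 1 (adjusted p = 0.063) and with genes of more than 1 list left out (0.069), and its median was −0.14 without control 3 and −0.61 without morphant 2. The notch call was lost without control 3 (median −0.11), morphant 1 or morphant 2 (highest adjusted p 0.079), and its median was −0.28 without control 2. Notch medians from the control mean were 0.09, −0.22 and 0.06 in controls 1 to 3 and −0.14, −0.30 and −0.19 in morphants 1 to 3. Control 2 thus lay below morphants 1 and 3. By edgeR, 1 of the 31 notch members had an unadjusted p under 0.05. The wnt median was −0.10 without control 1 and −0.36 without morphant 2.

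Blood genes were higher in the morphants. The blood and endothelium list had 36 members with a median of 0.83 (camera adjusted p = 1.6e-05, and adjusted p = 0.50 with an estimated correlation). By edgeR no member passed over all genes or adjusted over the list alone, and 15 members were above all controls in all morphants. DESeq2 called 2 higher, hbbe2 (adjusted p = 0.0046) and hbae5 (0.032). The embryonic globin gene hbbe2 stood at 6.90 ± 5.41 CPM in controls and 62.5 ± 53.7 in morphants (log2 fold change 3.18, SE 0.89), and hbae5 at 1.80 ± 1.31 and 11.4 ± 9.09 CPM (2.65, SE 0.85). Their edgeR adjusted p-values were 0.33 and 0.38. Globin genes are near-identical copies, and their counts may be split between them. The list stood lowest in the scrambled control, at −0.71 from the control mean, and at 0.59 and 0.31 in controls 2 and 3, against 0.95, 0.83 and 0.63 in morphants 1 to 3.

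Genes of the p53 pathway and apoptosis were higher (33 members, median 0.41, camera adjusted p = 0.0038, and adjusted p = 0.50 with an estimated correlation), with 0 members past the edgeR threshold over all genes and 0 adjusted over the list alone. DESeq2 called 1 higher, sesn1 (adjusted p = 0.020). The stress-response gene sesn1 stood at 26.2 ± 3.49 CPM in controls and 56.8 ± 2.81 in morphants (log2 fold change 1.12, SE 0.25, edgeR adjusted p = 0.21) and casp8 at 4.94 ± 1.66 and 12.9 ± 5.35 CPM (1.39, SE 0.41, adjusted p = 0.35). The p53 targets cdkn1a and mdm2, chosen after their values were seen, had log2 fold changes of 0.03 (SE 0.33) and 0.30 (SE 0.36). The list median was 0.27 without morphant 1. With the scrambled control as the only control, a lone sample assumed to vary like the morphants, the list's median was 0.31 and its adjusted p 0.14.

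Genes of anterior structures outside the dissected region (20 members, median 0.21, camera adjusted p = 0.0070, and adjusted p = 0.51 with an estimated correlation) and ribosomal protein genes (79 members, median 0.37, adjusted p = 0.015, and adjusted p = 0.97 with an estimated correlation) were higher. By edgeR neither had a member past the threshold over all genes or adjusted over the list alone, and DESeq2 called 1 anterior and 0 ribosomal members higher. The former, en2b (adjusted p = 0.0076), was chosen after its values were seen and its low counts kept it out of the genes tested by edgeR. In the anterior list mab21l2 stood at 0.544 ± 0.323 CPM in controls and 2.03 ± 0.69 in morphants (log2 fold change 1.95, SE 0.61). In the ribosomal list rpl37 (0.94, SE 0.43) and rpl5a (0.39, SE 0.25) had the smallest p. The medians of both lists were high in morphants 1 and 3 and low in morphant 2, with anterior medians of 1.76, −0.24 and 1.29 and ribosomal medians of 0.90, −0.69 and 0.48 in morphants 1, 2 and 3. The anterior median was 0.0073 without morphant 1 (adjusted p = 0.12), 0.081 without control 1, and 0.41, 1.01, 0.39 and 0.36 without control 2, control 3, morphant 2 and morphant 3. The anterior call was also lost on log2(FPKM + 1) (median 0.51, adjusted p = 0.10), on log2(FPKM + 0.1) (1.31, 0.054) and with 1 surrogate variable (0.11, 0.052), and its median was 1.29 in the design with 3 levels. The ribosomal median was −0.0049 without morphant 1 and 0.67 without morphant 2, and the call was also lost without control 1 or morphant 3. With the length trend removed, a step added after the data were seen, the ribosomal median was 0.20 (adjusted p = 0.11) and the anterior median 0.11 (0.015).

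**Figure D4:**
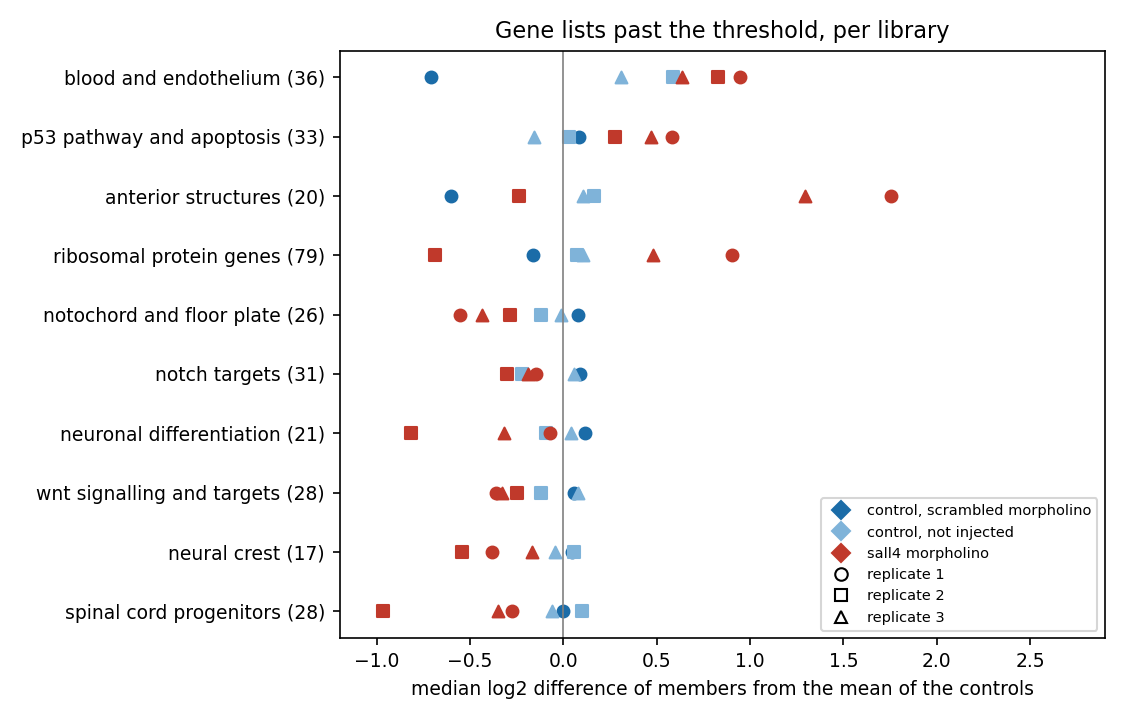
Median log2 difference of each list's members from the mean of the 3 controls (horizontal) for the 10 lists past the threshold (vertical, number of tested members in brackets), 1 point per library. For spinal cord progenitors the morphants lie between −0.97 and −0.28 and the controls between −0.06 and 0.10.

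The other 18 lists did not pass, and by edgeR no member of them passed over all genes. DESeq2 called nkx1.2la, srl and mta1 lower and crabp2a, sox17 and fabp2 higher, the last chosen after its values were seen. The fry test, whose p asks whether the genes of a list moved one way on balance, called 0 of the 28 lists (smallest adjusted p 0.18). Neuromesodermal and tailbud progenitor genes (19 members, camera adjusted p = 0.75) had a median of 0.13, a mean of −0.04 and a test direction down, with 1 member lower adjusted over the list alone, nkx1.2la (139.7 ± 35.2 and 58.0 ± 5.003 CPM, log2 fold change −1.27, SE 0.28). The gene gdf11 stood at 40.8 ± 1.31 and 83.3 ± 21.7 CPM (1.03, SE 0.28). The tailbud genes tbxta (−0.28, SE 0.27), tbx16 (0.19, SE 0.28), cdx4 (0.13, SE 0.33) and msgn1 (0.45, SE 0.47) did not pass, and their groups overlapped. Their edgeR adjusted p-values were 0.70, 0.81, 0.88 and 0.73. For tbxta, morphants 2 and 3 (460.9 and 500.4 CPM) lay below all controls, and morphant 1 (690.4 CPM) did not. The lists of posterior presomitic mesoderm (median −0.02, mean 0.06, test direction up, adjusted p = 0.97), anterior presomitic mesoderm and somite formation (median −0.07, adjusted p = 0.34) and skeletal muscle (median 0.14, adjusted p = 0.92) held aldh1a2, the retinoic acid-synthesising enzyme gene (59.3 ± 16.1 and 25.6 ± 8.39 CPM), tbx18 (2.49 ± 0.48 and 5.68 ± 1.64 CPM), srl (log2 fold change −1.60) and actc1b (1.44) among the members with the smallest p. Of the posterior presomitic genes, her11 had a log2 fold change of 0.84 and tbx6 one of −0.56.

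The hox genes of paralogue groups 1 to 8 (24 members, median 0.0034, test direction down, adjusted p = 0.89) and 9 to 13 (23 members, median 0.21, adjusted p = 0.35) had members on both sides. The transcript of hoxb4a stood at 44.6 ± 8.06 CPM in controls and 21.5 ± 1.57 in morphants (log2 fold change −1.05, SE 0.26), and hoxb8a at 25.9 ± 0.93 and 43.4 ± 3.58 CPM (0.74, SE 0.24). The values were −0.92 (SE 0.39) for hoxa13a and 0.87 (SE 0.42) for hoxd13a. Among signalling lists, fgf (median −0.14, adjusted p = 0.25), retinoic acid (−0.18, adjusted p = 0.34) and bmp (−0.18, adjusted p = 0.16) did not pass. Their leading members were fgfr1b (−0.99), fgfr3 (−0.82), crabp2a (1.22), stra6 (1.96), nog2 (−0.78) and bmp7b (−1.23). The transcript of crabp2a, a retinoic acid-binding protein gene, stood at 257.8 ± 17.3 and 599.7 ± 164.1 CPM.

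Endoderm and hindgut (median 0.98, adjusted p = 0.20), interferon (0.24, adjusted p = 0.14), pronephros (median 0.01, mean 0.03, test direction down, adjusted p = 0.73), epidermis and periderm (median 0.02, mean −0.04, test direction down, adjusted p = 0.25) and the sall family (median −0.03, adjusted p = 0.75) did not pass. Endoderm passed under 7 of 24 alternatives, among them without control 3 (adjusted p = 0.0019) and without morphant 2 (0.020). Interferon passed under 6, among them without control 2 (0.039), and its median was −0.037 without control 1. Adjusted over the list alone, the endoderm gene sox17 was higher (0.326 ± 0.174 and 1.56 ± 0.43 CPM) and foxa1 was lower, and sall3b was higher in the sall list, which also held sall2 (−1.09). The smallest p in the other lists belonged to the interferon-responsive genes stat1a (1.27) and isg15 (1.37), the pronephric genes irx1b (−1.03) and hnf1ba (−0.98), and the epidermal genes krt4 (−0.95), a keratin, and dlx3b (−0.66). Cell cycle genes (44 members, median 0.17, adjusted p = 0.76), pluripotency-associated factors (median −0.07, adjusted p = 0.087), the nurd complex (median 0.08, mean −0.09, test direction down, adjusted p = 0.25) and extracellular matrix genes (median 0.34, mean 0.16, test direction down, adjusted p = 0.76) did not pass either. In the nurd list mta1, a subunit of the chromatin complex, was lower adjusted over the list alone (31.8 ± 4.49 and 13.1 ± 2.13 CPM, log2 fold change −1.28, SE 0.28, edgeR adjusted p over all genes 0.21). The collagen gene col1a2 stood at 366.2 ± 112.2 and 161.6 ± 22.6 CPM (−1.18, SE 0.31, adjusted p = 0.29), and col5a1 had a log2 fold change of −1.02. The values were −0.65 for the cyclin gene ccnd2a, −0.61 for the replication gene mcm7, −1.35 for prdm14, 0.86 for myca and −0.89 for gatad2ab.

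The scrambled-injected control was set against the 2 non-injected controls to describe what the injection itself accompanied. With 1 library on one side there is no replicate check and no p-value. Between the scrambled control and the mean of the others 940 genes differed by more than 2-fold, 281 higher and 659 lower. Between single libraries the numbers were 1765 for the scrambled control against control 2, 871 against control 3 and 1151 between controls 2 and 3. The blood and endothelium median was −1.06 in the scrambled library, below all of 10000 random lists of the same size and expression (percentile 0), and hbbe2 stood at 1.303 CPM against 12.102 and 7.31. The anterior list had a median of −0.91 and the endoderm list one of −0.62 (both percentile 0). Hox groups 1 to 8 (−0.37), hox groups 9 to 13 (−0.36) and ribosomal protein genes (−0.24) also lay at percentile 0. The difference of control 2 from control 3, both non-injected, was smaller for endoderm (−0.39, percentile 0.14) and blood (0.18, percentile 99.0), and for epidermis (0.31) and hox groups 9 to 13 (0.23) it lay at percentile 100. Random lists lack the joint movement of real list members, so an extreme percentile does not measure how rare a difference is. For spinal cord progenitors the median was −0.0017 (percentile 48.2) and for the p53 list 0.12 (percentile 94.9). Against the 2 non-injected controls alone, the 3 morphants had 0 genes past the edgeR threshold. The unadjusted p was under 0.05 for 865 of 18457 tested genes, a share below the 0.05 that chance would give. The fit against the scrambled control alone has 1 library on one side, so its counts are left out here.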

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

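Directions and calls were recomputed under 24 settings, of which the removal of a length trend, the same without morphant 2, voom quality weights and 1 surrogate variable were chosen after seeing the data. The fits with only the non-injected controls and without control 1 are the same fit and are counted as 2 settings. Of 1619 values of 68 named genes 1358 kept direction and side of the threshold, 178 came past it, 55 no longer passed and 28 turned. Only the 5 genes past the threshold in the main fit could lose a call, so all 55 losses are theirs. They passed under 15 (adra1ba), 13 (col18a1b, prg4a and tph1b each) and 11 (avpr1ab) of 24 alternatives. Of 672 values of 28 lists these numbers were 556, 24, 45 and 47, and only the 10 called lists could lose a call. Spinal cord, wnt, blood and p53 lists kept their call without each library in turn. Lists were tested on log2 CPM or FPKM, so DESeq2, robust settings and the fold floor gave no list values, and DESeq2 values without an adjusted p were left out. The smallest library held 18626513 counts, which limits genes of low level such as sall1b. Where no cause is given below, the cause was not tested.

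With the replicate number as a replicate block 0 genes passed (0 higher), sox2 was −0.14, the anterior structures median 0.98 and the posterior presomitic median −0.032. The block changed none of the 10 list calls and brought 1 more list past the threshold, endoderm (adjusted p = 0.038). Deviations of same-numbered samples correlated at −0.294, −0.0951 and 0.16, and not every sample correlated best with its own number, so numbers were not taken to pair the samples.

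The count of genes past the threshold (5, all higher) was 1 (1 higher) with library-size scaling, with cdx4 −0.0040, sox2 −0.16 and posterior presomitic −0.11. It was 28 (23 higher, 5 lower) with no filter, with sox2 −0.011 and pronephros 0.13, where more genes were tested. It was 9 (8 higher, 1 lower) with at least 1 CPM in all samples of a group, with skeletal muscle 0.14 and pronephros −0.61 (camera adjusted p = 0.079). It was 334 (180 higher, 154 lower) by DESeq2 and 1 (1 higher) with a fold floor of 1.5. On log2(FPKM + 1) it was 11 (10 higher, 1 lower), with sox2 −0.15, sall family 0.0048, posterior presomitic −0.0357 and pronephros −0.62 (camera adjusted p = 0.055). On log2(FPKM + 0.1) it was 12 (10 higher, 2 lower), with −0.15, 0.0036, −0.0361 and −0.66 (camera adjusted p = 0.059) for these. Without an FPKM filter it was 0 (0 higher), with sox2 −0.15 and posterior presomitic −0.031. A list can count as turned with its median unchanged in sign, where the test direction turned.

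With only the 2 non-injected controls 0 genes passed (0 higher), cdx4 was −0.052, sox2 −0.069, posterior presomitic −0.079 and skeletal muscle 0.045. With only the scrambled control, where the lone sample is assumed to vary like the morphants, 0 passed (0 higher), sall4 was 0.14, neuromesodermal progenitors 0.40, hox groups 1 to 8 0.17 and pronephros 0.71. In the design with 3 levels 0 passed (0 higher), with sall4 0.022, hox groups 1 to 8 0.0773 and pronephros 0.0768. Without genes of more than 1 list, the notochord call was lost (adjusted p = 0.069), anterior presomitic was 0.082, neuromesodermal 0.14 and pronephros 0.16. Of the 18 lists that did not pass, endoderm passed under 7 alternatives (adjusted p 0.00032 against the lone scrambled library, otherwise at least 0.0015), interferon under 6 (0.0017 against that library, otherwise at least 0.0061), pluripotency under 5 of which 2 are the same fit (lowest 0.017), bmp under 2 (0.038), epidermis under 2 (0.029), and hox groups 9 to 13 (0.0076) and extracellular matrix (0.020) under 1 each, without morphant 2. The list count of 10 fell to 0 with estimated correlations and to 0 by fry, and otherwise lay between 7 and 12.

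With the length trend removed 20 genes passed (17 higher, 3 lower), with sall4 0.19, sox2 −0.053, posterior presomitic 0.11 and extracellular matrix 0.32. With it removed and morphant 2 left out 1042 passed (575 higher, 467 lower), with sall4 0.45, anterior presomitic 0.032, cell cycle 0.015, neuromesodermal 0.15 and sall family 0.17. With voom quality weights 7013 passed (3300 higher, 3713 lower), with sall4 0.094, anterior presomitic −0.046, cell cycle −0.037 and posterior presomitic 0.011. The weight of morphant 2 was 0.136 and that of morphant 3 was 5.53, so this fit rested on few libraries. With 1 surrogate variable 1161 passed (499 higher, 662 lower), with sox2 −0.26, posterior presomitic −0.068 and extracellular matrix 0.14.

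Leaving out each library in turn gave 0 to 1534 genes (0 to 742 higher, 0 to 792 lower), the largest counts without morphant 2. Ranges were −0.12 to 0.12 for sall4, −0.40 to 0.33 for sox2, −0.12 to 0.29 for cdx4, −0.12 to 0.78 for msgn1, −0.27 to 0.43 for sall1a and −0.045 to 0.29 for tbx16. List medians ranged from −0.27 to 0.12 (sall family), −0.12 to 0.23 (neuromesodermal), −0.079 to 0.18 (posterior presomitic), −0.24 to 0.029 (anterior presomitic), 0.045 to 0.21 (skeletal muscle), −0.16 to 0.089 (hox groups 1 to 8), −0.13 to 0.41 (hox groups 9 to 13), −0.086 to 0.33 (pronephros), −0.13 to 0.26 (cell cycle), −0.29 to 0.55 (extracellular matrix), −0.31 to 0.089 (nurd), −0.33 to 0.11 (epidermis), −0.45 to −0.059 (pluripotency), −0.037 to 0.37 (interferon), −0.27 to −0.034 (retinoic acid), −0.23 to −0.055 (fgf), −0.29 to −0.10 (bmp), 0.65 to 1.40 (endoderm) and −0.0049 to 0.67 (ribosomal protein).

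The 940 genes with over 2-fold difference in the scrambled library became 2491 with no filter, 468 with the stricter filter, 234 on log2(FPKM + 1), 521 on log2(FPKM + 0.1) and 281 without an FPKM filter. Without control 2, control 3 or each morphant in turn the count lay between 1018 and 1897, the largest without control 3.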

Other observations

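The genes of the first paragraph, the mixed fry test, the shares of spinal cord and of blood and vascular mesoderm, and the condition on length in the test for cells of other regions were chosen after the results were seen. Library correlations with length and list medians had also been seen before the tests below were written.

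Among genes with an edgeR adjusted p between 0.05 and 0.10, the fin fold gene and2, which encodes an actinodin of the fin fibres, stood at 4.58 ± 2.85 CPM in controls and 80.9 ± 21.4 in morphants (log2 fold change 4.15, adjusted p = 0.054). The glutamate receptor gene grin2da stood at 53.026 ± 15.8 and 358.8 ± 101.5 CPM (2.76, adjusted p = 0.068). The pigment gene tyrp1a stood at 2.79 ± 0.49 and 0.053 ± 0.046 CPM (−5.43, adjusted p = 0.054), and the glutamate transporter gene slc1a2b at 3.64 ± 1.37 and 0.278 ± 0.078 CPM (−3.66, adjusted p = 0.079). The wnt antagonist notum1b, like notum1a, was low, at 125.8 ± 52.5 and 19.5 ± 7.65 CPM (−2.69, adjusted p = 0.13). The mixed fry test, which asks whether genes of a list moved in either direction, called 9 of 28 lists. Its adjusted p was 0.0039 for spinal cord progenitors, for neural crest and for hox groups 1 to 8, and 0.0054 for neuromesodermal progenitors.

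Spinal cord progenitor genes were lower, and a smaller share of spinal cord in the piece would lower them alike if all came from it alone. Their mean squared deviation from a common change was 4.945 in squared standard errors, with 22 lower and 6 higher. Over 14 neural tube members it was 4.75, with 12 lower and 2 higher and a weighted mean of −0.92, against −0.59 for the whole list. The members thus did not share 1 change. Since 5 members also belong to other lists, and parts of the spinal cord may be lost unequally, the test cannot exclude a smaller share. The transcript length trend as fitted did not carry the fall, with 97.73% of the median change left after its removal. The list's median log2 relative length was 0.038, near that of the median gene, so this removal could move the median little. A difference in stage was not tested and stays open, as do a smaller share and a response to the morpholino.

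The blood and endothelium list was higher, through its red cell members. A larger share of blood-forming and vascular mesoderm together would raise both, and the endothelial median (0.017, 12 members) was 0.8759% of the red cell median (1.92, 20 members), so the rise was not shared. The length trend as fitted did not carry it, with 104.5% of the median change left after its removal. The list's median log2 relative length was 0.27, so this removal was a weak test. A larger share of red blood cells alone, a difference in stage and an effect of injection, which rests on 1 scrambled library, were not tested. Red cell medians were −1.91, 1.08 and 0.72 in controls 1 to 3 and 3.22, 1.15 and 2.25 in morphants 1 to 3.

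Morphants 1 and 2 deviated from their group mean in opposite directions (correlation −0.896). Deviations from a group's own mean cancel out for each gene, so a negative correlation is partly built in. It was −0.448 for morphants 2 and 3 and 0.0039 for morphants 1 and 3. Removing the length trend left 80.6% of the variance among morphants, against a bound of 80%. The 95% interval over 1000 resamples of genes, which are not replicates, was 79.56 to 81.66 and holds that bound. The trend as fitted thus left most of the variance, but the verdict by the bound is not secure. For cells of other regions, 0.5987% of abundant genes lay 4-fold or more below every control in morphant 1 or 2. Of these genes 25 were low in morphant 1 and 2 in morphant 2. The highest share for a control against the other 2 controls was 0.35%. As first written the low share in the morphants would have counted for that cause. With the condition on length added after the values were seen, because these genes were mostly long mRNAs, the test cannot tell.

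Of the 10 splits of the 6 libraries into 3 and 3, 2 gave at least the 5 genes of the real split, and 10 splits cannot give a share under 0.05. The highest other count was 13, with controls 1 and 2 and morphant 2 against the rest, and points to a structure of the samples other than their groups. At an unadjusted p under 0.05 the real split gave 1719 genes, and 2 others gave 1913 and 3371.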
